A study of Mus musculus with 12 samples.

How the data were processed

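Small RNA abundance was measured in spleens of female mice that received ovalbumin (OVA, an egg-white protein used as a model allergen) or normal saline by intraperitoneal injection. Per the labels, mice of 8 weeks were injected 3 times, on days 1, 3 and 5, with 0.05 mg OVA per day in the OVA arm, and spleens were taken on day 14 or day 28. OVA-specific IgE was measured in blood, and animals with high levels were chosen for the arrays, so the OVA arrays describe mice selected for their antibody response. There were 4 OVA arrays and 2 saline arrays at each day, 12 in all. The labels number the arrays of a group as replicates without tying each one to its own mouse. The p-values therefore measure only the spread between these arrays.

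Per the labels' protocols, total RNA that kept the small RNA fraction was isolated from frozen spleen and labelled with biotin by an Affymetrix FlashTag kit. The deposited table holds 1 processed intensity per probe set and array on a linear scale, from 0.627 to 24076. The summarisation, background correction and normalization that the authors used are not given in the sources used here, and neither are scan dates or array batches. The median intensity lay between 1.03 and 1.09 on every array, so most of the 36249 probe sets sat at a common floor. The mean intensity ran from 40.6 to 51.7, so the upper part of the distribution was not equal between arrays. The table holds no detection p-values. As a working limit of background, the 0.1 percentile of each array was mirrored around that array's median log2 intensity, which gave log2 limits of 0.54 to 0.72. Between 5807 and 6842 probe sets per array lay above that limit. The small number of arrays limits the precision, with 2 saline arrays per day.

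The files pair the numeric probe-set identifiers with no miRNA name, species or sequence, and the gene table used here does not list them. The miRNA lists and the plant background probe sets fixed before the data were examined could therefore not be applied, and no list test was made. The rule set in advance for this case was used instead. Probe sets whose mean log2 intensity over the 12 arrays reached the median of all probe-set means (0.05) were tested, 18125 in all. For the same reason only the 2 probe sets with the largest higher and the 2 with the largest lower log2 fold change among those past the threshold are named, for OVA against saline at each day. Where several probe sets had identical values, the first identifier stands for them. This shortens the rule for named miRNAs that was fixed in advance, which allowed more names. Identical values on all 12 arrays were frequent: 14174 probe sets shared their values with at least 1 other, and the whole table held 25112 distinct profiles. Counts are therefore given for probe sets and for distinct profiles.

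The intensities were converted to log2 without a pseudocount, since none was 0 or below. A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the saline groups shared the estimate of the spread with the OVA groups. Each probe set had 8 residual degrees of freedom and 4.39 prior degrees of freedom. From this fit came OVA against saline at day 14 and at day 28, the difference between these effects, their mean, and day 28 against day 14 within each arm. All tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Bright probe sets are those with a mean log2 intensity of at least 4 (2828 probe sets, 998 distinct profiles). They were used for principal components and for correlations across profiles.

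The procedure was tested on simulated data with the means and spreads of the 18125 tested probe sets, of which 200 with a mean log2 intensity of at least 2 were changed. The low-intensity probe sets, the larger part of those tested, were therefore not covered. Of changes of 1 log2 unit, 39.0% were recovered in the day 14 design and 45.0% in the day 28 design. Of changes of 2 log2 units, 91.0% and 86.5% were recovered. False calls numbered 1 to 11 per simulation. The noise was drawn independently for each probe set, whereas real probe sets often had identical values. The simulated counts of false calls need not hold for the real arrays.

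Other settings were the replicate number as a block, quantile normalization or median centring of the tested probe sets, no level filter or one 1 log2 unit higher, an intensity trend with robust variances, array weights, a fit to the compared groups alone, a fold minimum of 1.5, unadjusted p-values and leaving out each array. Where this left 1 saline array at a day, that array was assumed to vary like the other groups. After the data were seen, 9 further settings were added, among them 1 probe set per distinct profile, scaling on the bright probe sets, and removal of OVA day 28 replicates 3 and 4. Adding stem-loop probe sets could not be tried without names.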

Results

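Expression of small RNAs was compared between spleens of OVA-injected and saline-injected mice at 2 time points after sensitisation. The 12 arrays comprised 4 OVA and 2 saline arrays at day 14, and 4 OVA and 2 saline arrays at day 28. Probe sets are given by the array's identifiers, because the files do not pair them with miRNA names. Of the 18125 probe sets tested, 12816 had a mean log2 intensity under 1, close to the floor of the array, and 2828 were bright, with a mean of at least 4. Among the 998 distinct bright profiles, arrays of 1 group correlated at Pearson r of 0.975 to 0.987 in OVA day 14 and 0.973 to 0.994 in OVA day 28. Mean intensity over all probe sets ran from 40.6 to 51.7 per array. It was highest in the 4 OVA day 28 arrays (47.4 to 51.7). The saline day 28 arrays stood at 41.0 and 40.9, and the day 14 arrays of both arms at 40.6 to 44.8. The single pairs of saline arrays correlated at 0.987 at day 14 and 0.985 at day 28. Some pairs from different groups correlated as closely. Of the 12 arrays, 9 were closest to an array of their own group and 3 to one of another group. OVA day 14 replicate 4 and saline day 14 replicate 1 were closest to each other (r = 0.991), and saline day 28 replicate 2 was closest to OVA day 14 replicate 2 (r = 0.987). OVA day 14 replicate 4 correlated at 0.975 to 0.981 with its own group.

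The largest source of variation between the arrays was a single component that held 63.7% of the variance of the bright profiles. The day 28 arms lay at its opposite ends. They also differed in mean intensity over all probe sets (47.4 to 51.7 in OVA, 41.0 and 40.9 in saline). Whether the component reflects the spleens or the brightness of the arrays was not tested. The saline day 28 arrays scored -12.7 ± 0.10 (SD, n = 2) and the OVA day 28 arrays 10.7 ± 7.2 (SD, n = 4). The day 14 arms lay between them and in the other order, with OVA at -5.59 ± 4.8 (SD, n = 4) and saline at 2.51 ± 2.4 (SD, n = 2). Within OVA day 28, replicates 3 and 4 scored 16.5 and 17.3 and replicates 1 and 2 scored 3.45 and 5.55. Within OVA day 14, replicate 4 scored 1.38 and the other arrays -9.22 to -6.71. These high-scoring replicates also had the highest mean intensity of their groups. At day 28 it was 51.7 and 51.2, against 47.4 and 49.0 for replicates 1 and 2. At day 14 it was 44.3, against 40.6 to 42.6. The saline day 14 arrays ran the other way, with 44.8 at a score of 0.84 and 43.5 at 4.19. The arms did not overlap at day 28, with a two-sided exact permutation p of 0.067, the smallest that 4 against 2 arrays allow. The exact permutation p was 0.20 at day 14 and 0.029 for OVA day 28 against OVA day 14. Adjusted over the 5 exact tests of array scores, these exact p-values were 0.11, 0.25 and 0.11 for day 28, day 14 and the OVA arrays over time.

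**Figure D1:**
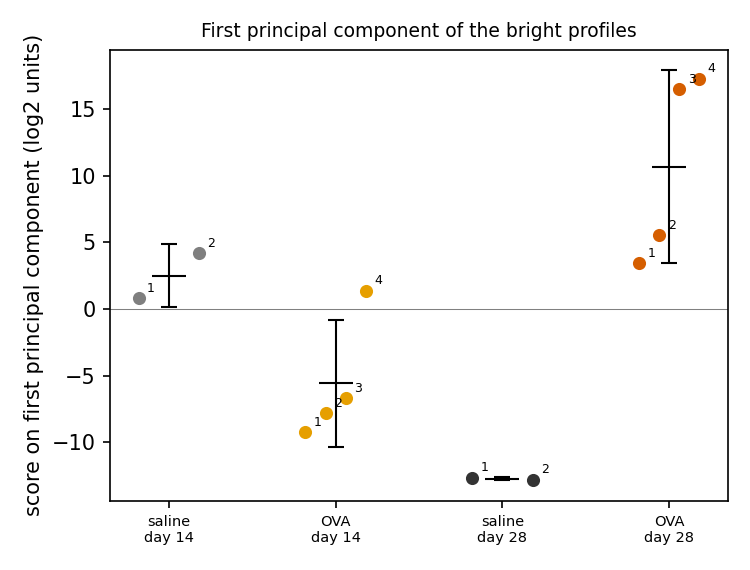
Score of each array on the first principal component of the 998 bright distinct profiles (y axis, log2 units, sign arbitrary) by group (x axis). Points are arrays with their replicate number, and bars are the group mean and SD. The saline day 28 arrays sit near -12.7, and OVA day 28 replicates 3 and 4 lie above 16.

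The first comparison asked which small RNAs differed in the spleen 14 days into the protocol. A single abundance profile, shared by 9 probe sets with identical values (the first is 20503803), was the main difference. It stood at a log2 intensity of 4.42 ± 0.38 (SD, n = 4) in OVA spleens and 1.95 ± 0.41 (SD, n = 2) in saline spleens, 5.56-fold higher (log2 fold change 2.47, SE 0.29, limma adjusted p = 0.0027). Probe set 20523650 was 2.94-fold higher, at 2.48 ± 0.41 (SD, n = 4) against 0.92 ± 0.15 (SD, n = 2), with a limma adjusted p of 0.036. All 4 OVA arrays lay above both saline arrays for each. These 10 probe sets were the only ones called among 18125, all of them higher in OVA and none bright. With replicate numbers as a block, which the arrays' deviations did not bear out as pairs, 157 were called, 87 higher and 70 lower. Saline day 14 was the low group for 20503803 and 20523650. Saline spleens at day 28 stood at 3.43 ± 0.47 (SD, n = 2) for 20503803 and 2.11 ± 0.16 (SD, n = 2) for 20523650, against 4.23 ± 0.34 (SD, n = 4) and 1.98 ± 0.23 (SD, n = 4) in OVA day 28. Without saline day 14 replicate 1, no probe set passed limma's adjusted threshold, and 1246 had an unadjusted p under 0.05. The log2 fold changes were then 2.18 for 20503803 and 1.45 for 20523650, near those with all arrays. Testing each distinct profile once called 1, that of 20503803. Without an adjustment, 1346 probe sets of the full fit had a p under 0.05, 697 higher and 649 lower. No probe set was called when only the bright ones were tested, where 348 had an unadjusted p under 0.05 in limma.

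The second comparison, OVA against saline at day 28, gave a broad difference. Small RNAs of 2101 probe sets differed, 1754 higher and 347 lower in OVA spleens, which corresponds to 441 higher and 208 lower distinct profiles. Testing each distinct profile once called 475. Of the called probe sets, 1143 of the higher and 228 of the lower were bright. The median log2 fold change was 1.13 among the higher and -1.01 among the lower probe sets, and 1040 and 175 of them differed by at least 1 log2 unit.

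The most strongly higher probe set, 20518417, was abundant. It stood at 9.06 ± 1.5 (SD, n = 4) in OVA against 5.44 ± 0.11 (SD, n = 2) in saline spleens at day 28, 12.3-fold higher (log2 fold change 3.62, SE 1.0, limma adjusted p = 0.039). The log2 fold change was 4.33 without OVA day 28 replicate 1 and 2.38 with replicate numbers as a block. Its level varied from array to array in OVA day 14 as well (7.74 ± 1.9, SD, n = 4). Probe set 20505113 was 10.6-fold higher (log2 fold change 3.41, SE 0.56, limma adjusted p = 0.0024), at 4.40 ± 0.94 (SD, n = 4) against 1.00 ± 0.17 (SD, n = 2). Saline day 28 was the lowest group for both. Saline day 14 stood at 7.94 ± 0.14 (SD, n = 2) for 20518417 and 3.50 ± 0.51 (SD, n = 2) for 20505113. In the opposite direction, 20513478 was 6.66-fold lower, at 1.35 ± 0.46 (SD, n = 4) against 4.09 ± 0.49 (SD, n = 2), with a limma adjusted p of 0.0058. Without saline day 28 replicate 2 its limma adjusted p was 0.058, in a range of 0.00064 to 0.48 over all settings. Probe set 20534320 was 6.38-fold lower, at 1.88 ± 1.1 (SD, n = 4) against 4.55 ± 0.04 (SD, n = 2), with a limma adjusted p of 0.046. The calls of 20518417, 20534320 and, at day 14, 20523650 were lost in 15 of 29, 16 of 27 and 20 of 27 other settings. In 13, 14 and 18 of these the log2 fold change stayed within 1 SE of its value above. Settings that change only the filter, the estimate of the spread or arrays of the other day cannot move it. These counts are therefore no test of its size. Testing each distinct profile once moved their limma adjusted p to 0.075, 0.087 and 0.090. Over all these settings it ranged from 0.0070 to 0.98, from 0.019 to 0.82 and from 0.015 to 0.66.

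Part of the profiles called at day 28 also differed between day 14 and day 28 by limma's adjusted p, fewer of them in saline, with 2 arrays per day, than in OVA. Of the 441 higher profiles, 267 rose over time in OVA and 46 fell in saline. Of the 208 lower ones, 69 fell in OVA and 16 rose in saline. The median log2 changes over time were of similar size in both arms. They were 0.70 in OVA and -0.60 in saline for the higher profiles, and -0.51 and 0.65 for the lower. These profiles were chosen on the day 28 arrays, which favours such directions over time. With the saline spleens of both days together as the control, 2083 probe sets were called at day 28, 1832 higher and 251 lower, and 1816 of them were among the 2101. The count fell to 976 without saline day 28 replicate 1 and to 987 without OVA day 28 replicates 3 and 4. The excess of higher over lower calls depended on scaling: quantile normalization of the tested probe sets gave 1092 higher and 671 lower, and centring each array on its bright probe sets gave 1321 higher and 1928 lower, after shifting all log2 fold changes by -0.31.

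**Figure D2:**
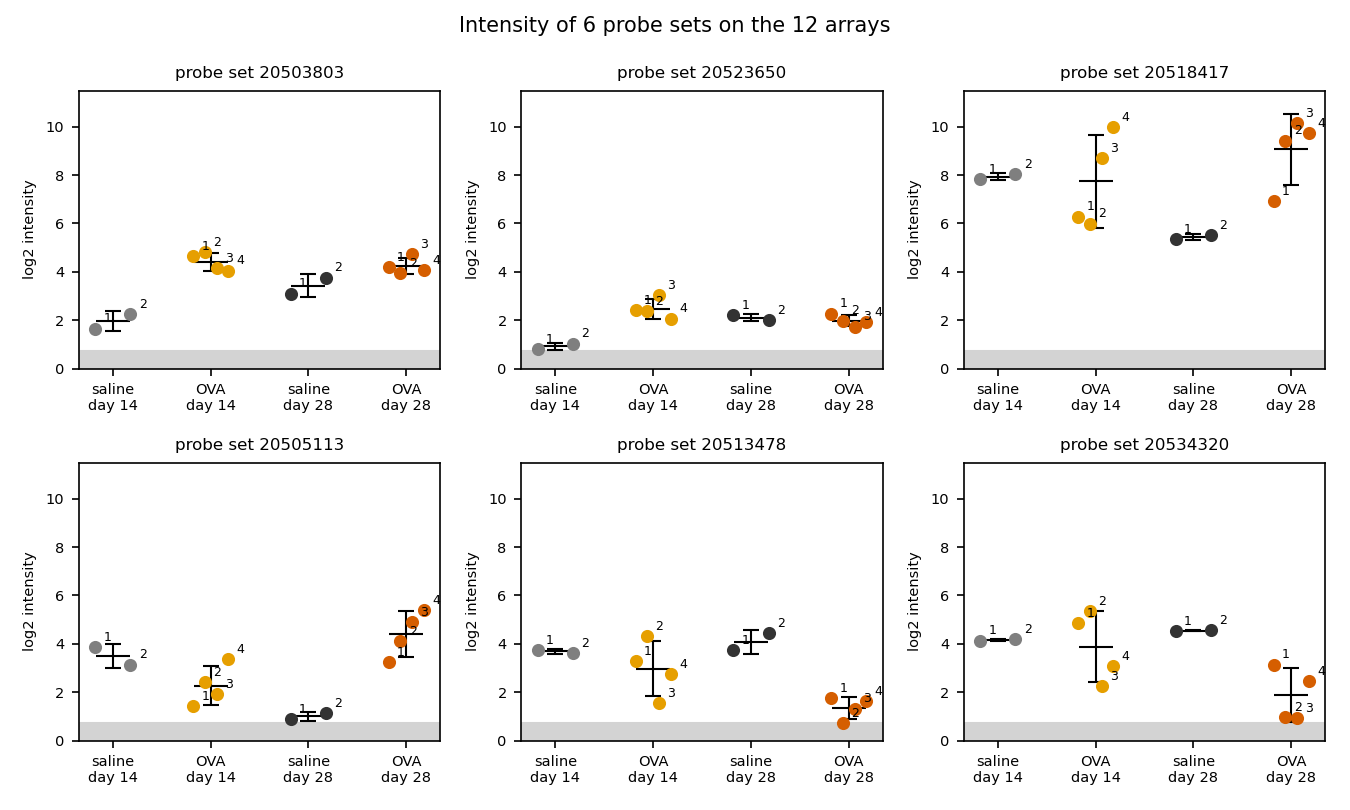
Log2 intensity (y axis) of the 6 named probe sets on every array, by group (x axis). Points are arrays with their replicate number, bars are the group mean and SD, and the grey band lies below the highest background limit of any array (0.72). Probe set 20503803 is lowest in saline day 14, and 20518417 spreads widely within both OVA groups.

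The third comparison asked whether the OVA effect differed between the days. It did so for 1715 probe sets in limma's test of the difference itself, 1398 with a higher and 317 with a lower effect at day 28. Testing each distinct profile once called 328. Of the 503 distinct profiles behind these calls, 316 were higher in OVA at day 28 and lower at day 14, and 176 the reverse. Selection for a large difference favours opposite signs, and among all 998 bright profiles 76.8% had them. For 20505113, the effect was 3.41 at day 28 and -1.22 at day 14, a difference of 4.63 log2 units (SE 0.79, limma adjusted p = 0.0046). The probe sets named at day 14 had a smaller effect at day 28. Naming probe sets for a large effect at 1 day favours a large difference between the days. The difference was -1.67 log2 units for 20503803 (SE 0.41, limma adjusted p = 0.019) and -1.69 for 20523650 (SE 0.33, limma adjusted p = 0.0075). For 20518417 and 20513478, the difference between days did not pass the threshold (limma adjusted p = 0.15 for each), nor did it for 20534320 (0.26). The count was 917 without saline day 14 replicate 2, 997 without saline day 28 replicate 1, and 1100 without OVA day 28 replicates 3 and 4. Quantile normalization of the tested probe sets gave 1004 higher and 567 lower, and centring on the bright probe sets 953 higher and 1112 lower, after a shift of -0.36.

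Across the 998 bright distinct profiles, the OVA effects at the 2 days were negatively correlated (Pearson r = -0.73, Spearman rho = -0.72), and 766 profiles (76.8%) had opposite signs. The days share no arrays. Profiles are not independent replicates, so the arrays were reassigned to arms within each day, and 13 of the 225 assignments gave an r of that size or more, an exact permutation p of 0.058. Pearson r ranged from -0.79 to -0.64 when 1 array was left out. It was -0.66 without OVA day 28 replicates 3 and 4.

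**Figure D3:**
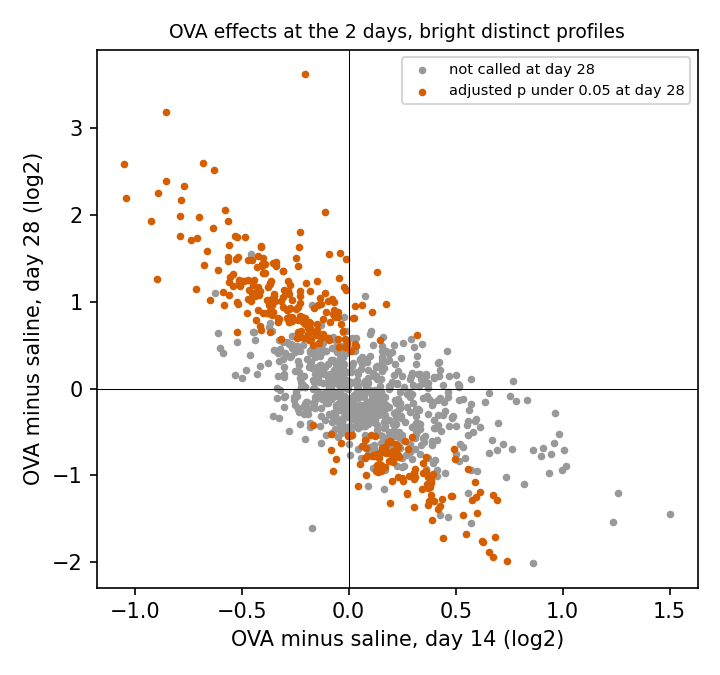
OVA minus saline log2 difference at day 14 (x axis) and day 28 (y axis) for the 998 bright distinct profiles. Orange points are the 324 profiles called at day 28, and grey points the 674 others. The cloud runs from upper left to lower right (Pearson r = -0.73).

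Averaged over both days, OVA and saline spleens differed in 109 probe sets, 107 higher and 2 lower in OVA, which form 18 distinct profiles. Testing each distinct profile once called 2. The profile of 20503803 was 3.12-fold higher (log2 fold change 1.64, SE 0.20, limma adjusted p = 0.0055), with all 8 OVA arrays above all 4 saline arrays. Of the 18 profiles, 13 were also called at day 28 and 1 at day 14. The count was unstable. It was 1 without saline day 28 replicate 1, 12 without saline day 14 replicate 2, 49 without saline day 14 replicate 1, 53 without OVA day 28 replicate 3, and 10 without OVA day 28 replicates 3 and 4. It was 9 with replicate numbers as a block.

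In OVA spleens, 1644 probe sets differed between day 28 and day 14, of which 1449 rose and 195 fell (351 and 106 distinct profiles). Testing each distinct profile once called 276, 228 that rose and 48 that fell. Bright probe sets made up 1000 of those that rose and 165 of those that fell. The median log2 change was 0.88 among the first and -0.83 among the second. Probe set 20505113 rose 4.38-fold (log2 change 2.13, SE 0.46, limma adjusted p = 0.011), and 20513478 fell 3.08-fold (log2 change -1.62, SE 0.45, limma adjusted p = 0.041). Without OVA day 28 replicates 3 and 4, limma called no probe set, and 2308 had an unadjusted p under 0.05. The median log2 change of the 351 profiles that rose was then 0.66, against 0.85 with all arrays, and each kept its sign. These profiles were chosen in the fit to all arrays, which favours a kept sign and size. The count was 899 without OVA day 28 replicate 3 and 990 without replicate 4. Quantile normalization of the tested probe sets gave 729 that rose and 428 that fell, and centring on the bright probe sets 998 and 422, after a shift of -0.16.

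In saline spleens, 230 probe sets differed between the days, of which 36 rose and 194 fell (28 and 47 distinct profiles), and 160 of those that fell were bright. With each distinct profile tested once, 29 were called, 10 that rose and 19 that fell. The median log2 change was 1.40 among those that rose and -1.31 among those that fell. Of the named probe sets, 20503803 and 20523650 had log2 differences of 1.48 and 1.19, with limma adjusted p of 0.051 and 0.054. Probe sets 20518417 and 20505113 had larger ones, -2.50 for each, with limma adjusted p of 0.39 and 0.088. For 20513478 and 20534320 they were 0.40 and 0.39, with limma adjusted p of 0.91 and 0.95. Of 34 distinct profiles called over time in both arms, 2 moved in the same direction. This comparison rests on 2 arrays against 2. The count was 8 without saline day 14 replicate 2, all of them rising, 9 without saline day 28 replicate 1, all rising, and 27 without saline day 14 replicate 1, 10 rising and 17 falling. It was also 137 without OVA day 28 replicate 3, 142 without replicate 4 and 356 without OVA day 14 replicate 4, arrays that enter only through the pooled spread. Centring on the bright probe sets gave 98 that rose and 102 that fell, after a shift of 0.20, and a fit to the 4 saline arrays alone called 21.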

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

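The day 28 tests below of a shared axis, of scaling and of OVA day 28 replicates 3 and 4 were chosen after the results were seen, and the criterion for replicates 3 and 4 was changed to include the fold after its result was seen, which did not alter the reading at day 28. None of the 20 checks for an array far from the others within an OVA group found one. Yet OVA day 14 replicate 4 correlated more closely with saline day 14 replicate 1 (r = 0.991) than with its own group (0.975 to 0.981). It scored 6.47 on the axis described below, against -8.59 to -4.48 for the rest of its group. That axis was drawn from the day 14 arrays, this one included, so the score is not separate evidence. What stood out was a difference between the days in the OVA effect, in 1715 probe sets by the test of the difference itself. Among the named probe sets it held for 20503803 (-1.67 log2 units, day 28 minus day 14), 20523650 (-1.69) and 20505113 (4.63). These were named for a large effect at 1 of the days, which favours a large difference. Of 100 of the 225 splits of the arrays within days, 2, the real one included, gave as many calls of the difference. This share is not adjusted for the other counts of splits made here. The highest other split gave 1751 and differed from the real one only in exchanging OVA day 14 replicate 4 with saline day 14 replicate 2. It kept the day 28 arms, and the other drawn splits that kept them gave 0 to 267 calls. Chance in the day 14 labels is therefore not excluded as a source of the difference.

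The first pattern is the broad day 28 difference, for which the real split of the 6 day 28 arrays, the only 1 with so many calls, gave 2101 and the highest other 646, in which OVA replicates 3 and 4 trade places with the saline arrays; 15 splits are too few for a share under 0.05. Scaling between arrays is argued against as the whole cause, since 91.0% of the 1371 bright calls kept their sign and their call after quantile normalization of the bright probe sets. These 1371 probe sets form 324 distinct profiles. The role of OVA day 28 replicates 3 and 4 stays open: without them 46.5% of the called probe sets remained. Both shares count identical probe sets separately and were not taken by distinct profile. The median log2 fold change of the 441 higher profiles was 0.91 (SE 0.23) against 1.09 (SE 0.23). These profiles were chosen in the fit to all arrays, which favours a kept size. An axis on which arrays of 1 group also differ is a candidate explanation. The day 28 effects correlated across profiles at r = 0.67 with the first axis of the deviations within the day 14 groups. Leaving out 1 day 28 array gave 0.62 to 0.69, but the axis was not redrawn without any day 14 array. Its sign was set to make r positive, so only the size of r is informative. The day 28 arms do not overlap on that axis (OVA 0.63 to 11.3, saline -10.3 and -8.55), so using it as a covariate decides nothing, and a response to OVA along the same axis, in mice selected for high IgE, stays open and untested.

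The second pattern is the opposite direction of the OVA effects at the 2 days. Chance assignment of arrays within days is not excluded, since 13 of 225 assignments gave a correlation as strong, the strongest other one reaching 0.78 in size. Projecting out the first axis of the deviations within groups, which held 42.8% of the variance within groups, moved the correlation from -0.73 to -0.31. That lies between the bounds set beforehand, above -0.2 if the axis were the cause and at most -0.5 if not, so whether the shared axis alone gives the opposite effects may not be decided here. A true reversal of the response between day 14 and day 28 stays open.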

How the results depend on the processing

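Settings described as added were chosen after the data were seen: distinct profiles, bright probe sets, scaling on them, removal of 2 arrays, the offset, pooled saline and the axis covariate. The miRNA list tests and the setting with stem-loop probe sets were not run, because the files pair no names with the identifiers, and a fit to the compared groups alone gives nothing further for the difference and the mean, which use all groups. Of the 18125 probe sets, 12816 had a mean log2 intensity under 1, close to background, and simulated changes did not cover them. For each of the 6 comparisons, 13 to 25 settings gave a count within 1.5 times the main one in the same direction. In 5 to 15 settings the count moved further. The majority turned in 1 setting at day 28, 1 for the difference and 3 in saline over time. Leaving out an array outside a comparison acts only through the pooled spread, so not every setting changed the compared arrays. The calls of 20505113, 20503803, 20513478, 20518417, 20534320 and 20523650 were kept in 26, 25, 25, 14, 11 and 7 settings and lost in 1, 2, 2, 15, 16 and 20. Replicate numbers did not pair the arrays: of 14 pairs of arrays with the same number in different groups, 3 correlated above 0.1 in their deviations (range -0.12 to 0.25), and 3 of 12 arrays correlated best with their own number. With the number as a block the counts were 157 at day 14 (87 higher, 70 lower), 1684 at day 28, 2030 for the difference, 9 for the mean of both days, 1905 in OVA and 419 in saline over time. Leaving out 1 array gave 0 to 10 calls at day 14, 976 to 2215 at day 28, 917 to 2066 for the difference, 1 to 160 for the mean, 899 to 1878 in OVA and 8 to 356 in saline over time. For saline, the direction turned without saline day 14 replicate 2 (8) and without saline day 28 replicate 1 (9). Unadjusted p-values under 0.05 numbered 1346, 3773, 3515, 2483, 3466 and 2525 in that order, and distinct profiles 1, 475, 328, 2, 276 and 29. Centring on the bright probe sets reversed the majority at day 28 (3249 calls) and for the difference (2065). It shifted all log2 fold changes, by -0.31 and -0.36. Testing bright probe sets alone gave 0 at day 14, 9 for the mean and 632 in saline. Quantile normalization of these gave 0 at day 14, 0 for the mean and 392 in saline, and that of the tested probe sets 10 for the mean. An offset of 16 before the log2, which shrinks dim probe sets, left 0 at day 14 and 0 for the mean. The zeros had 348, 428, 724, 1159 and 2298 unadjusted limma p-values under 0.05: bright at day 14, quantile at day 14 and mean, offset at day 14 and mean. Intensity trend with robust variances gave 22 for the mean and 415 in saline, the stricter filter 388 in saline, and a fit to the saline arrays alone 21. Without OVA day 28 replicates 3 and 4 the counts were 987 at day 28, 1100 for the difference, 10 for the mean, 0 in OVA (2308 unadjusted in limma) and 385 in saline. Without replicates 1 and 2 instead they were 1085 for the mean and 376 in saline, and 2136 in OVA. The axis covariate gave 0 at day 28, for the difference and in OVA over time (1614, 1335 and 2232 unadjusted), 50 for the mean and 7 in saline, all rising. It also turned the day 28 effect of 20518417 to -0.092 log2 units. The day 28 arms do not overlap on this covariate, which takes up the difference between them, so these losses do not bear on the cause, and the median day 28 effect was 0.62 (SE 0.29) against 1.03 (SE 0.22). The cause of the reversed majorities and of the other changes was not tested.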

Other observations

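The tests below of a difference shared by all arrays and of OVA day 28 replicates 3 and 4, and the count of splits at day 14, were chosen after the results were seen, and the criterion for replicates 3 and 4 was changed after its result was seen, which turned the reading for OVA spleens over time from explained by these arrays to open. Calls at day 28 became more frequent with abundance. They made up 1.43% of the 12816 probe sets with a mean log2 intensity under 1, 16.8% of the 1359 from 1 to 2, 28.4% of the 1122 from 2 to 4, 44.8% of the 1713 from 4 to 8, and 54.1% of the 1115 at 8 and over. Counted by distinct profile, the shares were lower: 1.28% of 9343, 12.2% of 757, 16.8% of 673, 30.7% of 714 and 37.0% of 284, in the same order. At day 14 the 10 calls lay from 1 to 4. The 18124 probe sets left out of the tests had group means of at most 1.56 in intensity, and none lay above the background limit on all arrays of an OVA group. The number of probe sets above the limit per array was 6761 ± 94.4 (SD, n = 4) in OVA day 28 and 6281 ± 247 (SD, n = 4) in OVA day 14. It was 6277 ± 288.5 (SD, n = 2) in saline day 14 and 6244.5 ± 619 (SD, n = 2) in saline day 28, where the arrays had 6682 and 5807.

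The third pattern is the change from day 14 to day 28. In OVA spleens, the real split was the only 1 of the 35 splits of the 8 arrays that gave any calls (1644, highest other 0). This share is under 0.05 but is not adjusted for the other counts of splits made here. For the first principal component of the same arrays, the exact permutation p was 0.029, and 0.11 after adjustment. Chance is therefore not firmly excluded. A difference between the days shared by all arrays, such as a processing batch common to both arms, is argued against as the main cause. It would move both arms alike. A batch that differed between the arms would not, and it was not tested. The changes in the OVA and saline arms correlated at r = -0.68 across bright profiles (-0.72 to -0.62 leaving out 1 array, -0.52 without OVA day 28 replicates 3 and 4). This r was not set against reassigned arrays, and the saline change rests on 2 arrays against 2. A smaller shared shift beneath these changes is therefore not excluded. By the first criterion, the share of calls left, OVA day 28 replicates 3 and 4 would account for the OVA change. Without them 0 percent of the OVA calls remained. By the criterion with the fold their role stays open. The median log2 change without them was 0.66 (SE 0.20) against 0.85 (SE 0.18) for the profiles that rose. For those that fell it was -0.54 against -0.79. These profiles were chosen in the fit to all arrays, which favours a kept size. Without replicates 1 and 2 instead, as many arrays were left. The median rise was then 1.09 (SE 0.19), and calls were not lost. The number of arrays alone therefore does not account for the loss.

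For the 4 against 2 comparison at day 14, 1 of the 15 splits, the real one, gave 10 calls or more and the highest other gave 5, and 15 splits are too few for a share under 0.05. For the mean of both days, 5 of 100 drawn splits within days gave at least the 109 calls observed, the real one included, so chance is not excluded. The highest other split gave 742 and kept the day 28 arms while OVA day 14 replicates 1 and 4 took the place of the saline day 14 arrays. A split that exchanged only OVA day 14 replicate 1 with saline day 14 replicate 2 gave 429. Each drawn split with more calls than the real one (742, 429, 177 and 152) kept the day 28 arms and changed only day 14 labels. Other drawn splits that kept these arms gave 52 and 0. The real day 14 effects ran against those at day 28 (Pearson r = -0.73), and opposite effects shrink their mean. Relabelling day 14 can therefore raise the count, and how far this accounts for it was not tested.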
